A study of Homo sapiens with 18 samples.

How the data were processed

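RNA from Ovcar5, a human ovarian cancer cell line, was measured on 18 Affymetrix expression arrays. Per the labels' protocols, cells received virus over 48 h, rested for 24 h and were selected with 2 µg/ml puromycin for 7 days, and 1 µg of total RNA was labelled with biotin after priming with oligo(dT). The labels give 3 groups of 6 replicates, each called biological. B2 and B6 are separate shRNAs against IKBKE, the gene of the kinase IKKe, and SC4 is a negative control shRNA by the titles and treatment labels, although the description field of those arrays names it as an IKKe shRNA. How far the replicates were separate infections is not said, so the p-values measure the spread between these arrays.

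The deposited table holds log2 values made with GCRMA, per the submitters' processing notes, for 54675 probe sets. GCRMA corrects the background, normalizes between arrays and summarises the probes of a probe set. In the table the median over the 18 arrays is 0, within 1e-06, for 54675 of 54675 probe sets, so each value is a difference from that median and carries no absolute level. The log base is not stated in the file and was taken as 2. If another base had been used, every fold would change and no p-value would. The signal over background of a gene cannot be read from centred values, and the number of arrays limits the precision. The within-group SD has 1 mode of probe sets that hardly vary, and an SD of 0.04 was taken as the border between these and the rest.

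Of the probe sets, 41091 had 1 gene symbol in the probe table, 1801 had several, 11721 had none there and 62 were controls of the array maker. Only those with 1 symbol entered the gene tests. They cover 19775 genes, 10523 of them with several probe sets. The design fixed before the data were examined took the probe set with the highest mean and a filter on low values. Centred values have no such mean and no low values, so no filter was applied, and a gene was represented by its probe set with the largest variance over the 18 arrays, which had been listed as an alternative. This choice does not use the group labels but favours probe sets that differ between groups, and the probe set with the largest within-group SD was therefore run as well.

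All 18 arrays entered 1 linear model with 3 group means (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 15 residual degrees of freedom). B2 and B6 were each compared with SC4, and B2 with B6. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 19775 genes. A gene called with both shRNAs in the same direction was counted as shared, the rule the design text gives for candidates. For 30 gene lists fixed before the data were examined, limma's camera with a preset inter-gene correlation of 0.01 was the set test, with an estimated correlation and fry as alternatives, adjusted over the 30 lists. Entries of these lists that the probe table does not name were not analysed here, and 1 list is counted among the lists but not reported here. Member counts use the adjusted p over all genes. For the lists in the Results section, counts with all 18 arrays adjusted over the list alone are given beside them.

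Genes were named by a rule fixed before the data were examined. It takes IKBKE and, for each shRNA, the 10 called genes with the largest rise and the 10 with the largest fall whose 6 arrays all lie outside the SC4 range. For both shRNAs it takes the 12 that rose and the 12 that fell with the largest smaller change, for B2 against B6 the 6 higher and the 6 lower, and of each described list up to 4 called members per comparison and any member called in opposite directions. Symbols of unnamed loci, open reading frames, antisense genes and pseudogenes were tested and not named.

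The fit was tested on simulated data for the B2 comparison, with the measured SD of each of the 19775 genes, 200 genes changed by known amounts and the 34 genes of 1 list all raised by 0.3. Of 50 genes changed by 0.3 on the log2 scale 58% were recovered, of 50 changed by 0.6 90%, of 50 changed by 1 98% and of 50 changed by 2 100%. Among the other 19541 genes 10 were called, and camera called the raised list and 0 others. The genes were simulated as independent, so this does not test camera on lists whose members vary together. The comparisons with SC4 share the control arrays, so 100 simulations without any effect and the 20 ways of giving each shRNA 3 of the 6 control arrays were run. Alternatives covered the probe set of a gene, the normalization, the error model, the arrays in the fit, replicate number as a block, the threshold and each array left out in turn, and 4 more were added after seeing the data. Figures were drawn with matplotlib 3.10.9.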

Results

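Gene expression in Ovcar5 ovarian cancer cells carrying either of 2 shRNAs against IKBKE (B2 and B6) or the control shRNA SC4 was compared on 6 arrays per group. IKBKE encodes IKKe, a kinase related to the IkB kinases and to TBK1. The study's title places the kinase in invasion and metastasis, and its design text keeps as candidates the genes that both shRNAs changed. Values are log2 differences from each probe set's median over the 18 arrays, with the log base taken as 2. Correlations between arrays ran from 0.329 to 0.778 within groups and from -0.40 to -0.03 between groups. The centring on the 18 arrays itself lowers these correlations, so negative values between groups do not show opposed profiles. SC4 arrays lay farthest from the medians of the 18 arrays, with an SD over all probe sets of 0.220 ± 0.027 (SD, n = 6) against 0.141 ± 0.008 for B2 and 0.159 ± 0.010 for B6 (n = 6 each). That SD measures distance from these medians, not noise between replicates. Root mean square differences between replicates were 0.142 to 0.263 for SC4, 0.125 to 0.168 for B2 and 0.132 to 0.166 for B6.

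IKBKE, the targeted gene, was lower with both shRNAs on its more variable probe set. Its centred level was 0.88 ± 0.13 (SD, n = 6) with SC4, -0.04 ± 0.12 (n = 6) with B2 and -0.24 ± 0.21 (n = 6) with B6. IKBKE thus fell by 0.93 on the log2 scale with B2 (SE 0.09, limma adjusted p = 6.32e-07), to 52.6% of the control, and dropped by 1.13 with B6 (SE 0.09, adjusted p = 4.42e-08), to 45.8%. No B2 or B6 array reached the lowest SC4 array at 0.63. The difference between B2 and B6 was 0.20 (SE 0.09) and did not pass the test (adjusted p = 0.145). A second IKBKE probe set went the other way, with log2 changes of 0.66 (SE 0.07, limma adjusted p = 2.34e-06) with B2 and 0.24 (SE 0.07, adjusted p = 0.0165) with B6. With the mean of both probe sets the IKBKE change with B2 was -0.14 and not past the threshold (adjusted p = 0.17).

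**Figure D1:**
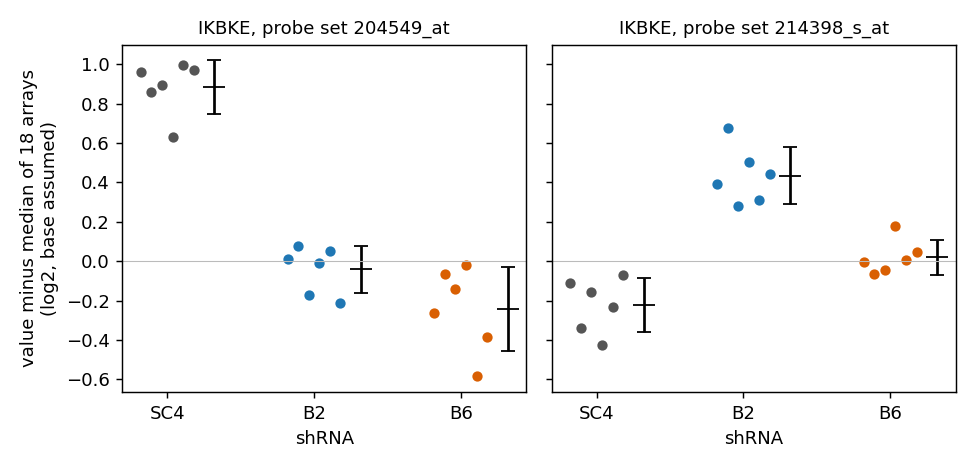
IKBKE on its 2 probe sets, as log2 value minus the median of the 18 arrays (vertical axis) for each shRNA (horizontal axis); points are arrays, bars the mean ± SD of 6 arrays. On the more variable probe set (left) the SC4 arrays lie at 0.63 or above and those of B2 and B6 at 0.08 or below, and on the second (right) the B2 arrays lie highest.

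With B2, genes of the amino acid and unfolded protein stress response were among the largest falls and genes of DNA replication rose. INHBE, which encodes an inhibin beta subunit, fell by 5.58 on the log2 scale (SE 0.21, adjusted p = 1.69e-11), and CTH, the cystathionine-cleaving enzyme of cysteine synthesis, fell by 3.88 (SE 0.21, adjusted p = 8.47e-10). The stress genes TRIB3 (-2.80), DDIT3 (-2.61), SESN2 (-2.60) and CHAC1 (-2.33) were among the 10 largest falls, together with AMIGO2 (-2.83), LURAP1L (-2.67), PXK (-2.46) and SPX (-2.35). The largest rise was that of ANGPT2, a ligand of the endothelial receptor TEK, at 4.26 (SE 0.11, adjusted p = 2.64e-13). It was followed by the matrix protease MMP9 (2.97), the cystatin CST1 (2.92), WIPF1 (2.92), CD69 (2.53), SERPIND1 (2.39), the cystatin CST4 (2.37), CDH5 (2.35), the collagenase MMP1 (2.33) and C2CD4A (2.29).

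In all, 4997 of 19775 genes were called between B2 and SC4, 2790 higher and 2207 lower. At a fold of at least 1.5 there were 1143. The 6 B2 arrays lay wholly outside the SC4 range for 15.2% of all genes, where chance gives 0.216%.

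By list, 36 of 40 measured G1/S and DNA replication genes rose with B2, 0 fell, and 38 rose when adjusted over the list alone. CCNE2, the gene of cyclin E2, rose by 1.58, the replication factor MCM10 by 1.46 and GINS1 by 1.33. The list's camera adjusted p was 3.67e-22, and its adjusted p = 0.0946 with an estimated correlation. Among 34 genes of G2/M and mitosis 23 rose and 2 fell (26 and 2 adjusted over the list alone), with KIF23 at 0.75, and at 0.24 on its other probe set, not past the test (camera adjusted p = 2.08e-05, adjusted p = 0.453 with an estimated correlation). Mean levels of this list were -0.21 to -0.11 in SC4 replicates 1 to 3 and -0.50 to -0.40 in SC4 replicates 4 to 6. Without SC4 replicates 5 and 6, a setting chosen after seeing the data, 16 rose and 1 fell with B2 (camera adjusted p = 0.000267). Of 33 unfolded protein and amino acid stress genes 20 fell and 6 rose, or 20 and 7 adjusted over the list alone (camera adjusted p = 9.63e-13, adjusted p = 0.0438 with an estimated correlation). Of 25 NRF2 and oxidative stress genes 18 fell and 1 rose, or 19 and 1 adjusted over the list alone, with camera adjusted p = 6.23e-16 and adjusted p = 0.00171 with an estimated correlation. The aldo-keto reductases AKR1B10 (-2.11), AKR1C2 (-1.80) and AKR1C1 (-1.62) and the transporter ABCC3 (-1.89) led that group.

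Growth factor and AP-1 early genes also fell with B2, 18 of 36 against 5 that rose, or 21 and 5 adjusted over the list alone (camera adjusted p = 5.57e-08, adjusted p = 0.0385 with an estimated correlation). EREG, a ligand of the EGF receptor, fell by 2.02, and the transcription factors ATF3 and KLF4 were at -1.69 and -1.63. On its other varying probe set EREG was at -0.02 with B2, not past the test (adjusted p = 0.528). Of 26 TGF-beta and YAP target genes 10 fell and 4 rose, the same numbers adjusted over the list alone, with AJUBA at -1.47 and F3, tissue factor, at -1.06 (camera adjusted p = 0.000374, adjusted p = 0.0812 with an estimated correlation). Among 39 type I interferon-stimulated genes 15 fell and 4 rose, or 19 and 6 adjusted over the list alone, led by IFI44L (-1.81), XAF1 (-1.39) and OASL (-1.14), with camera adjusted p = 0.000189 and adjusted p = 0.181 with an estimated correlation. Mean levels of these genes were 0.17 and 0.0711 in SC4 replicates 5 and 6 and -0.0677 to 0.0158 in the other SC4 arrays, and without those 2 arrays the median change with B2 was -0.11, against -0.19 with them (camera adjusted p = 0.0165). In the autophagy and lysosome list 11 of 30 fell and 2 rose, or 13 and 3 adjusted over the list alone, among them ULK1 (-1.25) and MAP1LC3B (-0.95), camera adjusted p = 0.000644 and adjusted p = 0.163 with an estimated correlation. Oxidative phosphorylation genes rose in 13 of 28 cases and 0 fell, with 13 also adjusted over the list alone, as for NDUFB8 (0.58) and COX4I1 (0.52, but 0.10 and 0.05 on its other 2 varying probe sets, the second not past the test), camera adjusted p = 0.00146 and adjusted p = 0.403 with an estimated correlation. These 9 lists were the ones camera called, a number that regrouped arrays also reach.

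With B6, the amino acid stress genes fell again and genes of cholesterol synthesis rose. INHBE fell by 5.73 (SE 0.21, adjusted p = 6.74e-12) and ASNS, asparagine synthetase, fell by 3.94 (SE 0.14, adjusted p = 4.13e-12). CHAC1 (-3.89), CTH (-3.80), JDP2 (-3.52), SESN2 (-3.50), BTF3L4 (-3.31), AMIGO2 (-3.24), PSAT1 (-3.17), an enzyme of serine synthesis, and TENM2 (-2.96) completed the 10 largest falls. The largest rise was that of GPRC5B, an orphan G protein-coupled receptor, at 3.78 (SE 0.08, adjusted p = 8.14e-15). ST6GALNAC5 (3.19), DHRS2 (2.85), the sterol synthesis enzyme MSMO1 (2.80), PIK3CG (2.51), ANGPT2 (2.24), SKP2 (2.15), ARHGDIB (2.13), ZNF595 (2.08) and HSPA2 (2.01) followed. Of the 19775 genes 5698 were called, 3449 higher and 2249 lower, with 1566 at a fold of at least 1.5. For 18.7% of all genes the B6 arrays lay wholly outside the SC4 range, where chance gives 0.216%.

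Cholesterol biosynthesis genes rose with B6 in 16 of 19 cases and 0 fell, or 16 and 1 adjusted over the list alone, with SQLE at 1.44 and INSIG1 at 1.35 beside MSMO1 (camera adjusted p = 1.77e-11, adjusted p = 0.0494 with an estimated correlation). In the fatty acid and lipid list 10 of 20 rose and 2 fell, or 11 and 2 adjusted over the list alone, with FASN, fatty acid synthase, at 1.18 and ELOVL6 at 0.72 (camera adjusted p = 0.008, adjusted p = 0.0756 with an estimated correlation). G1/S and DNA replication genes rose in 37 of 40 cases and 0 fell, with 38 adjusted over the list alone, for example CCNE2 (1.90), MCM10 (1.88) and FEN1 (1.57), with camera adjusted p = 4.08e-26 and adjusted p = 0.0756 with an estimated correlation. For G2/M and mitosis 27 of 34 rose and 0 fell, with 28 adjusted over the list alone, such as ANLN (1.22), KIF23 (1.13) and CCNA2 (1.13, the gene of cyclin A2), camera adjusted p = 5.56e-15 and adjusted p = 0.134 with an estimated correlation.

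The unfolded protein and amino acid stress list had 19 of 33 genes that fell with B6 and 7 that rose, or 20 and 7 adjusted over the list alone (camera adjusted p = 7.36e-10, adjusted p = 0.0756 with an estimated correlation). Growth factor and AP-1 early genes fell in 25 of 36 cases and rose in 4, or 26 and 4 adjusted over the list alone, with EGR1 at -2.31 and ATF3 at -2.20 (camera adjusted p = 1.31e-10, adjusted p = 0.0231 with an estimated correlation). TGF-beta and YAP targets fell in 10 of 26 cases and rose in 6, or 11 and 6 adjusted over the list alone, with AJUBA at -1.75 and BMP4 at 1.37 (camera adjusted p = 0.0176, adjusted p = 0.214 with an estimated correlation). F3, which fell with B2, was at 0.25 with B6. NRF2 genes fell in 12 of 25 cases and rose in 5, or 12 and 6 adjusted over the list alone, with camera adjusted p = 0.00902 and adjusted p = 0.214 with an estimated correlation. Without SC4 replicates 5 and 6, that camera adjusted p was 0.0543. For some lists SC4 replicate 4 went with them. TGF-beta and YAP targets averaged 0.08 to 0.11 in SC4 replicates 4 to 6 and 0.21 to 0.27 in SC4 replicates 1 to 3. Autophagy and lysosome genes averaged 0.15 to 0.22 and 0.02 to 0.05 in the same arrays. Oxidative phosphorylation genes rose in 13 of 28 cases and fell in 2, or 15 and 2 adjusted over the list alone, camera adjusted p = 0.000901 and adjusted p = 0.312 with an estimated correlation. The number of lists called with B6, 10 with 1 not reported here, is also reached by regrouped arrays.

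Lists named for invasion had members that moved in both directions. Of 33 matrix protease genes 9 rose and 6 fell with B2 and 8 rose and 7 fell with B6, or 11 and 6 and 8 and 7 adjusted over the list alone (camera adjusted p = 0.452 and 0.866). TIMP3, an inhibitor of matrix proteases, fell by 1.22 with B2 and fell by 0.96 with B6. The proteases MMP9 and MMP1 rose by 2.97 and 2.33 with B2 and by 0.661 and 0.715 with B6. Of 32 mesenchymal genes 3 rose and 8 fell with B2 and 6 rose and 8 fell with B6, or 4 and 10 and 6 and 8 adjusted over the list alone (camera adjusted p = 0.393 and 0.524). Fibronectin, FN1, fell by 1.05 with B2 and fell by 1.07 with B6, with 2 of its 6 varying probe sets not past the test. S100A4 rose by 0.88 and 0.94, and SNAI2, a repressor of epithelial genes, was at -0.66 with B2 and -1.04 with B6. Vimentin, VIM, was at -0.17 with B2 and 0.53 with B6, and the receptor kinase AXL at -0.26 (-0.05 on its other probe set, not past the test) and 0.58. Of 33 integrin and focal adhesion genes 9 rose and 6 fell with B2 and 9 rose and 9 fell with B6, or 11 and 7 and 9 and 9 adjusted over the list alone (camera adjusted p = 0.603 and 0.866), with ITGA2 at 0.86 and 0.96 and ITGB1 at -1.02 with B6, with 1 of its 4 varying probe sets, at -0.08, not past the test. Epithelial junction genes rose and fell 5 times each with B2 and rose 8 and fell 5 times with B6 among 30, the same numbers adjusted over the list alone (camera adjusted p = 0.603 and 0.752), and without SC4 replicates 5 and 6 8 rose and 2 fell with B2. Of 30 NF-kB targets 8 rose and 4 fell with B2 and 11 rose and 8 fell with B6, or 8 and 4 and 11 and 9 adjusted over the list alone (camera adjusted p = 0.559 and 0.752), with TNF at 1.83 and 1.27. The alternative test fry called matrix proteases (fry adjusted p = 1.18e-06), integrins (6.68e-05) and NF-kB targets (0.0158) up with B2. With B6 it called none of these (0.881, 0.604 and 0.238). Mesenchymal genes were called down by fry with B6 (0.0203) and not with B2 (0.457), and junction genes with neither (0.75 and 0.267). Among all 30 lists fry called 22 with B2 and 18 with B6.

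The design text asks which genes both shRNAs changed. The 12 strongest shared falls were INHBE, CTH, AMIGO2, TRIB3, DDIT3, SESN2, PXK, SPX, CHAC1, PSAT1, FUT1 and MAP2. Among them FUT1, a fucosyltransferase, was at -2.26 and -2.28 with B2 and B6, and MAP2, a microtubule-associated protein, at -2.16 and -2.58. The 12 strongest shared rises were ANGPT2, MSMO1, SKP2, ARHGDIB, LY96, PIK3CG, MRGPRX3, HSPA2, CCNE2, ECSCR, SH2D1B and NES. SKP2, which targets cell cycle inhibitors for degradation, rose by 1.80 and 2.15, LY96, a co-receptor of TLR4, by 1.76 and 1.87, and nestin, NES, by 1.90 and 1.49. MRGPRX3 was at 1.86 and 1.76, ECSCR at 2.18 and 1.57, and SH2D1B at 1.51 and 1.69. On 1 other varying probe set each, SKP2 was at 0.02 and 0.06 with B2 and B6, MAP2 at -0.15 and -0.17, PIK3CG at 0.25 with B2, and NES at 0.28 and ANGPT2 at 0.17 with B6, none past the test. Of the called changes of genes picked by the naming rule that had other varying probe sets, 45 of 104 with B2 and 48 of 119 with B6 had at least 1 of these not called or in the other direction, and for 28 with each shRNA no other one was called in the same direction.

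In all 3490 genes were called in the same direction with both shRNAs, 2085 higher and 1405 lower, and 186 in opposite directions. Independent lists of these sizes would share 486.6 higher and 251 lower genes, numbers that take no account of the shared control arrays. Simulations without effects shared 0, which follows from their setting, as few genes are called where none changes. Neither shows how far the shared controls add to the overlap. With B2 and B6 each set against 3 different SC4 arrays, 2187 to 2687 genes were shared over the 20 ways. Without SC4 replicates 5 and 6, a setting chosen after seeing the data, 3593 were shared. The changes correlated across genes at 0.744, against 0.500 in the simulations, with genes not independent replicates, and their covariance was 0.0783 against 0.0031. The share of all genes with the same sign in both comparisons was lower than in those simulations, 57.2% against 66.7%, and ran from 45.5% to 72.9% over the 20 ways. The simulations held no shift common to the genes of an array, whereas the median change of all genes was 0.0118 with B2 and -0.0031 with B6. For the 6322 genes that hardly vary (within-group SD under 0.04) such a shift can set the sign. The simulated share is therefore no measure of chance agreement here. Of the shared genes 1000 also differed between B2 and B6, and 716 of them changed more with B6. Camera called 7 lists in the same direction with both shRNAs. With an estimated correlation it called 1, growth factor and AP-1 early genes, lower with both (camera adjusted p = 0.0385 with B2 and 0.0231 with B6).

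**Figure D2:**
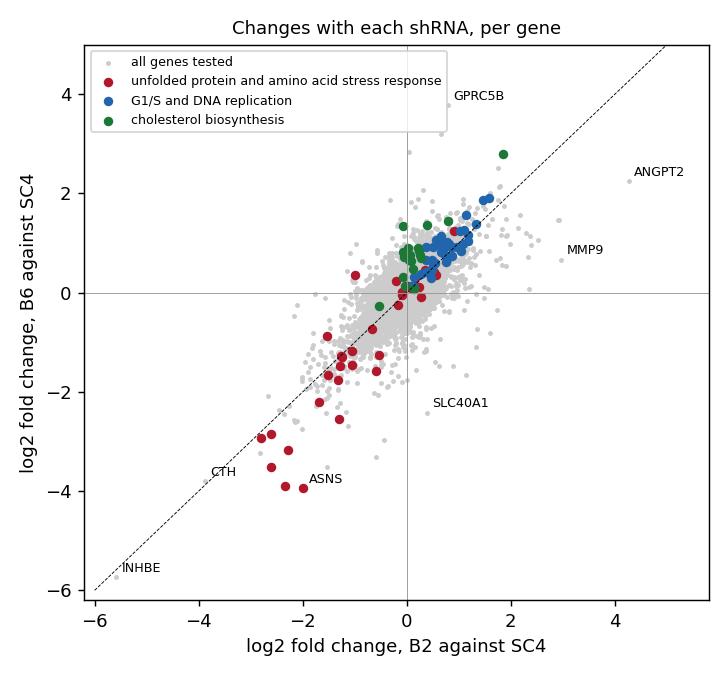
Log2 fold change of each of 19775 genes with B2 (horizontal axis) and B6 (vertical axis) against SC4, with 3 gene lists in colour and the line of equal change dashed. Of 33 stress genes 19 were called lower with both shRNAs and lie at the lower left, with ASNS at -1.99 and -3.94. Of 40 replication genes 36 were called higher with both and lie at the upper right. Cholesterol genes lie mostly above the line.

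Between B2 and B6, 3393 genes differed, 1426 higher with B2 and 1967 higher with B6. After quantile normalization 52.1% of the calls were higher with B2, against 42% as deposited. The iron exporter SLC40A1 was higher with B2 by 2.81 (SE 0.12, adjusted p = 5.36e-11), as it dropped with B6 (-2.42). CEACAM7 (2.81), BTF3L4 (2.72), TENM2 (2.52), osteopontin, SPP1 (2.42) and PAEP (2.40) were also higher with B2. GPRC5B (-2.99), DHRS2 (-2.79), ST6GALNAC5 (-2.54), SCG2 (-2.19), the collagen COL12A1 (-1.94) and TMT1A (-1.88) were lower with B2 than with B6. SPP1 rose by 1.32 with B2 and fell by 1.10 with B6, PAEP rose by 1.59 and fell by 0.81, and COL12A1 fell by 0.97 and rose by 0.97. The COL12A1 values rest on 1 of its 3 varying probe sets, and the other 2 were at 0.008 and 0.013 with B2 (adjusted p = 0.94 and 0.917) and at 0.24 and 0.18 with B6 (adjusted p = 0.0232 and 0.193). CEACAM7 and TMT1A differed between B2 and B6 on only 1 of 3 varying probe sets each.

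Cholesterol genes were lower with B2 than with B6 in 16 of 19 cases and higher in 0, or 18 and 0 adjusted over the list alone (camera adjusted p = 4.9e-17, adjusted p = 0.00863 with an estimated correlation). NRF2 genes were lower with B2 in 18 of 25 cases and higher in 1, the same numbers adjusted over the list alone, with AKR1B10 at -1.85 and ME1 at -1.05 (camera adjusted p = 1.85e-14, adjusted p = 0.00284 with an estimated correlation). Interferon-stimulated genes were lower with B2 than with B6 in 17 of 39 cases and higher in 0, or 18 and 0 adjusted over the list alone (camera adjusted p = 3.94e-10, adjusted p = 0.0276 with an estimated correlation). Against SC4, 18 of them rose and 4 fell with B6, or 19 and 6 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0623). Without SC4 replicates 5 and 6, a setting chosen after seeing the data, camera called it (adjusted p = 0.00181), and the median change with B6 was 0.23, against 0.11 with them. Of the members that led the fall with B2, XAF1 and IFI44L also fell with B6 (-1.54 and -0.82). OASL was at -1.14 with B2 and 0.44 with B6, IFIT1 at -0.17 and 0.32, ISG15 at -0.21 and 0.23, and HERC5 and the RNA sensor RIGI at 1.11 and 0.92 with B6.

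**Figure D3:**
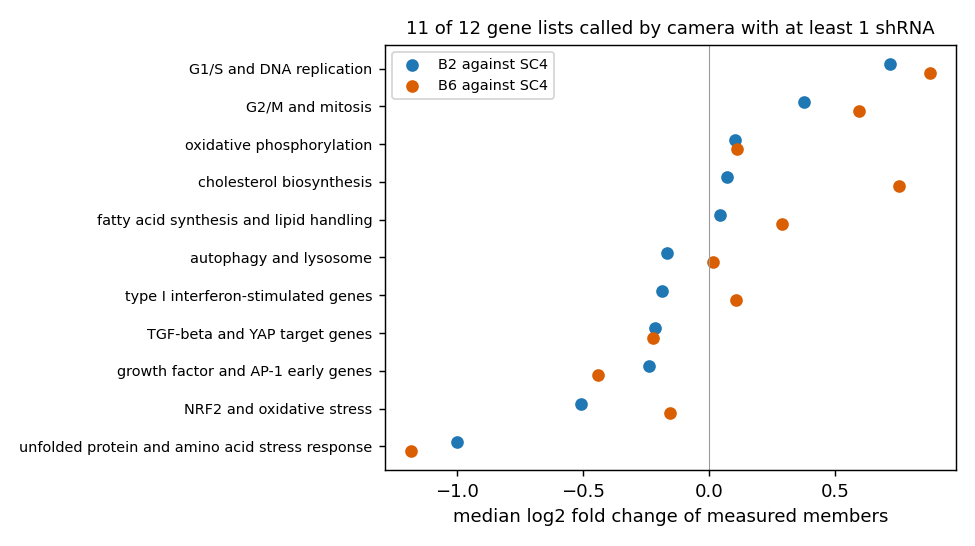
Median log2 fold change of the measured members (horizontal axis) of 11 of the 12 gene lists that camera called with at least 1 shRNA (vertical axis), for B2 and B6 against SC4; 1 called list is not reported here. Replication genes have medians of 0.72 and 0.88, stress genes of -1.0 and -1.18, and interferon-stimulated genes of -0.19 and 0.11, which were -0.11 and 0.23 without SC4 replicates 5 and 6.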

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

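The tests of regrouped arrays, of the reference genes, of interferon-stimulated genes and of the IKBKE probe sets were written down only after their results, or counts that bear on them, had been seen. The within-group correlation of stress and replication genes was written down before it was computed.

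In 100 groupings of the 12 arrays of a comparison, the real one included, 1 gave as many genes as the real one for B2 against SC4 (4490 genes in that fit, at most 263 in another grouping), 1 for B6 against SC4 (5378 against 6) and 1 for B2 against B6 (3976 against 15). For genes changed by both shRNAs, 1 of 100 groupings of the 18 arrays did so (3490 against 0). For these counts a chance labelling of the arrays is argued against, with 1 in 100 the smallest share that 100 groupings can give. Chance differences between cultures or infections were not tested. For the number of lists called by camera, chance cannot be excluded: 46 of 100 groupings gave as many as B2 (9 lists, up to 18 in another grouping), 19 as many as B6 (11 lists, up to 21) and 15 as many as both shRNAs (7 lists, up to 11). Camera with a preset correlation called lists in regrouped arrays too. Groupings that mix the groups unevenly keep part of the real difference, so these list numbers cannot tell chance from that difference. The member counts and the adjusted p with an estimated correlation carry more weight.

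Amino acid stress genes were lower and replication genes higher than SC4 with both shRNAs, all of this rests on 1 control shRNA, and with an estimated correlation only the stress list with B2 kept its camera call (adjusted p = 0.0438, against 0.0756 for stress with B6 and 0.0946 and 0.0756 for replication with B2 and B6). Scaling of whole arrays would shift both lists the same way. Their medians argue against it, at -1.0 with B2 and -1.18 with B6 for stress genes and 0.72 and 0.88 for replication genes. The 14 reference genes, with median changes of 0.02 with B2 and 0.13 with B6, add little, as GCRMA had already normalized between arrays. With B6, 8 of them rose. For the part of the change that the shRNAs share, a culture state that varies between dishes may contribute, since within groups arrays with lower stress genes had higher replication genes over 18 arrays (Pearson r = -0.64, permutation p = 0.0176, Spearman rho = -0.56, permutation p = 0.038, r = -0.66 without the 2 arrays farthest out), although r was -0.79 in SC4, -0.87 in B2 and 0.57 in B6. Loss of IKKe, an effect of the control shRNA and the state of the SC4 cultures all stay open.

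Type I interferon-stimulated genes were lower with B2 and as a list not with B6. If lower IKBKE mRNA had caused the fall of the list, the same genes would be expected to fall with B6, where IKBKE was at least as low, but of the 15 genes that fell with B2 4 fell with B6, 5 rose, and 10 were higher with B6 than with B2. SC4 replicates 5 and 6 had higher levels of these genes than the other SC4 arrays, and without them the B2 to SC4 comparison had a camera adjusted p of 0.0165 and B6 to SC4 one of 0.00181, in opposite directions. For the 4 that fell with both, among them XAF1 (-1.39 and -1.54) and IFI44L (-1.81 and -0.82), loss of IKKe stays open, and an effect of either shRNA on other targets was not tested and stays open.

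The 2 IKBKE probe sets changed in opposite directions. Opposite calls of a gene's probe sets were uncommon, in 5.55% of 1893 genes with 2 or more called probe sets for B2 and 4.26% of 2256 for B6. The second probe set is not among those that hardly vary, as its within-group SD was 0.126 against a border of 0.04. Whether its signal lies near background cannot be told from centred values. Signal from another transcript or from a virus sequence was not tested, and no biological explanation was tested.

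Besides cholesterol (camera adjusted p = 4.9e-17), NRF2 (1.85e-14) and interferon-stimulated genes (3.94e-10), 8 more of the 30 lists differed between B2 and B6. G2/M and mitosis (2.89e-11), fatty acid and lipid genes (3.18e-05), antigen presentation (0.000143) and G1/S and replication (0.000933) were lower with B2. Early AP-1 genes (0.00174), stress genes (0.0233) and leukocyte and endothelial markers (0.0456) were higher with B2, and autophagy and lysosome genes (0.0295) lower. With an estimated correlation the fatty acid list kept its call (adjusted p = 0.0113), and the other 7 of these 8 had adjusted p from 0.27 to 0.553.

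Of 420 groups of 6 arrays, 26 had 1 array far from the other 5 by Dixon's ratio, and chance gives about 1 in 20. IKBKE was 0.63 in SC4 replicate 4, against 0.86 to 0.99 in the others. Among list means, B6 replicate 4 had antigen presentation at 0.24, B2 replicate 4 epithelial adhesion at 0.18, and B2 replicate 1 mesenchymal genes at -0.0733. G2/M and mitosis in B2 replicate 3 was at 0.0663, hypoxia and glycolysis in B2 replicate 5 at -0.0778, autophagy in B6 replicate 3 at 0.0944 and reference genes in B6 replicate 1 at 0.14. The SD over all probe sets of B6 replicate 5 was 0.141. Among B2 arrays, replicate 4 stood out for INHBE (0.31) and IL11 (0.24), replicate 1 for ZNF595 (0.87), replicate 3 for ULK1 (-0.48) and replicate 5 for NDUFB8 (-0.0450). Among B6 arrays, replicate 6 stood out for CTH (-0.99) and VEGFA (-0.22), replicate 4 for WIPF1 (-0.72), replicate 1 for SPP1 (-0.27), and replicate 5 for DDIT4 (0.0012) and ULK1 (-0.63). Among SC4 arrays, replicate 3 stood out for SERPIND1 (-0.58), replicate 1 for GPRC5B (-0.54) and ME1 (0.17), replicate 6 for DHRS2 (-0.54), replicate 2 for HSPA2 (-1.79) and replicate 5 for TIMP3 (0.39).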

How the results depend on the processing

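The alternatives "no filter" and "probe set of largest variance" equal the reported setting, the filter at a level of 6 and a fold threshold on list counts were not run, and an intensity trend has no real intensity to follow in centred values. Within-group SD as filter or as choice of probe set, leaving out SC4 replicates 5 and 6, and a term for odd or even replicate number were chosen after seeing the data. With the mean of all probe sets, IKBKE changed by -0.14 with B2 (adjusted p = 0.17), as its probe sets oppose each other. Under array weights 6686 genes differed between B2 and B6, and at an adjusted p below 0.01 2194. A fold of at least 1.5, which only narrows the calls, left 1143 genes with B2, 1566 with B6, 728 with both and 638 between B2 and B6. With an estimated correlation 3 lists were called with B2, 2 with B6 and 1 with both, and with fry 22, 18 and 13. Leaving out 1 array at a time gave 4667 to 5054 genes with B2, 5346 to 5794 with B6, 3283 to 3598 with both, 2906 to 3878 between B2 and B6, 9 lists with B2, 10 to 13 with B6 and 6 to 7 with both, and IKBKE changes of -0.98 to -0.89 and -1.18 to -1.06. Same-numbered arrays of different groups deviated together by 0.165 at most, with 2 of 6 pairs of B2 and B6 over 0.1. With a replicate block 4758 genes were called with B2, 5467 with B6, 3359 with both and 3052 between B2 and B6, 9, 10 and 7 lists moved, and IKBKE changed by -0.93 and -1.13. Of 529 called changes of named genes, 401 kept direction and call under each alternative run, and of 30 called list results 9 did, as 21 lost their call with an estimated correlation and 0 turned. With the mean of probe sets TOP2A (-0.16) and TPP1 (0.0396) turned with B2. With the probe set of largest within-group SD, BID (0.0621), ERAP1 (-0.0157) and TPP1 (0.22) turned with B2, TIMP2 (0.57) with B6, and ERAP1 (-0.10), GUSB (0.0732) and TIMP2 (-0.0713) between B2 and B6. Where no reason is given, the cause was not tested.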

Other observations

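Other lists had members of note. Of 32 hypoxia and glycolysis genes 9 rose and 10 fell with B2 and 11 rose and 11 fell with B6 (camera adjusted p = 0.183 and 0.866), and VEGFA, an angiogenic factor, fell by 2.01 and fell by 1.78. DDIT4, an inhibitor of mTORC1 signalling, fell by 1.26 and fell by 1.27. Of 27 cytokine genes 7 rose and 5 fell with B2 and 8 rose and 7 fell with B6 (camera adjusted p = 0.761 and 0.739). IL32 rose by 1.53 and 1.14, while IL11 fell by 1.17 and fell by 2.41.

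Among 17 IKK-related kinases and adaptors 4 rose and 5 fell with each shRNA (camera adjusted p = 0.429 with B2 and 0.752 with B6). STING1, an adaptor of cytosolic DNA sensing upstream of TBK1, rose by 0.95 with B2 and by 1.62 with B6. ITGB3 was at 0.97 with B2 and 0.06, not past the test, with B6 (difference 0.91, adjusted p = 0.000125), with 1 of its 6 varying probe sets, at 0.16 with B2, not past the test.

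Of 14 commonly used reference genes 3 rose and 0 fell with B2, and 8 rose and 1 fell with B6 (camera adjusted p = 0.458 and 0.0552, and 0.0259 for B6 without SC4 replicates 5 and 6). Of 14 fibroblast and stromal markers 0 rose and 2 fell with B2, and 1 rose and 1 fell with B6 (camera adjusted p = 0.447 and 0.646). Of 16 leukocyte and endothelial markers 3 rose and 1 fell with B2, among them CDH5, and 1 rose and 1 fell with B6 (camera adjusted p = 0.45 and 0.531).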
